A study of Mus musculus with 4 samples.

How the data were processed

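The series holds 4 single-cell libraries of neutrophils from MOC1 mouse tumours, 1 each for control, trametinib, Egr1 wild type and Egr1 knockout, grouped by the treatment and genotype labels. Per the labels, each library combined 3 mice and aimed at 8000 cells with 10x Genomics 3′ chemistry. The labels differ on the isolation: the series design gives magnetic beads against Ly6G after a Percoll gradient, and the sample protocol gives flow sorting. The deposited values are raw counts of UMIs per gene and barcode, before any selection of cells. Per the submitters' processing notes the authors used Cell Ranger 8.0.1, FastQC, MultiQC and Seurat 4.0.1 with the mm10 build; the annotation release is not given in the sources used here. The labels also mention cell calling adjusted to neutrophils, whose thresholds are not given in the sources used here. Positions come from GENCODE vM21 on GRCm38, the same assembly as mm10, in which 32158 of 32285 feature IDs were found.

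A barcode was taken as a cell with at least 300 UMIs, at least 150 genes and at most 10% mitochondrial UMIs. This left 6838, 1620, 5083 and 1421 cells in the control, trametinib, wild-type and knockout libraries, 14962 in all. The median cell held 424, 1055, 416 and 1195 UMIs. Of the barcodes with at least 100 UMIs, 46.5, 86.6, 41.1 and 84.6% reached 300, so the minimum removed more barcodes from the unperturbed libraries. Genes seen in at least 10 cells were scaled to counts per 10000 and log-transformed, and the cells of the 4 libraries were clustered together with 2000 variable genes, 30 principal components, 15 neighbours and the Leiden algorithm at resolution 1 with seed 0. Of 20 clusters, 8 were neutrophil-like. A cluster took the class with the largest summed CPM of fixed markers, with at least 3 markers in at least 10% of its cells. Its 10 leading genes by fold, with 20 CPM added, could not hold more markers of another class than of its own. Limiting that last check to genes in at least 10% of the cluster's cells, and leaving a cluster unnamed at a tie, were chosen after seeing the data. That limit decided the class of cluster 1, with 2701 cells, because haemoglobin genes lead it without the limit and it would then have stayed outside the neutrophil-like class. Cluster 1 held 22.7% of the control, 1.58% of the trametinib, 40.4% of the wild-type and 1.21% of the knockout neutrophil-like cells. Scrublet marked 1, 4, 1 and 8 cells as doublets, too few to have worked, so doublets were not removed.

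Counts were summed over neutrophil-like cells per library, giving 2229560, 1482890, 1614827 and 1513593 UMIs, and expressed as CPM of that sum. A gene entered a comparison with at least 50 CPM in 1 of the libraries and at least 30 UMIs over both. Log2 ratios had 0.5 count added to each sum. Intervals are exact Poisson for sums, exact binomial (Clopper-Pearson) for shares and ratios, at 95%, and cover counting error only. A floor of 3 counts bounds folds against 0 UMIs. With 1 library per group no p-value was computed; genes are described by a 2-fold and lists by a 1.5-fold rule of size. The position of a list's median is its percentile among 10000 random lists of the same size drawn from 20 bins of expression, a description of these libraries. Free RNA was read from barcodes of 1 to 20 UMIs, and its share was estimated from keratin, collagen and haemoglobin genes of the marker lists, so cells rich in haemoglobin raise the estimate. Genes with near-identical copies, such as Hba-a1 and Hba-a2, are uncertain.

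The comparisons, gene rules, lists and alternatives were set before the data were examined, apart from 5 alternatives added after seeing the data. Named genes are the 10 highest and 10 lowest per comparison, leaving out sex-linked, mitochondrial and unnamed clone genes, up to 4 members of each pathway list with the largest absolute log2 ratio, and Egr1, Dusp6, S100a8, S100a9, Il1b, Cxcl2, Vegfa, Slc2a1, Arg2, Cd274 and Siglecf; the text gives a selection of them, and 1 gene is not reported here. Etv4 and the values in other cell classes were chosen after their values were seen. Exceptions set beforehand were Dusp6 in fibroblast-like cells and the immediate early list in epithelial tumour-like cells. The 18 pathway lists were neutrophil identity, immature neutrophil granule, tumour-associated neutrophil, hypoxia and glycolysis, ERK-dependent feedback, immediate early, EGR1 target, inflammatory cytokine and NF-kB, interferon response, immunosuppression and reactive oxygen, antigen presentation, apoptosis and survival, migration and adhesion, lysosome and lipid, unfolded protein and heat shock, cell cycle, RNA quality and stress, and sex-linked genes. The 12 cell type lists were the markers of neutrophils, macrophages or monocytes, dendritic cells, T cells, NK cells, B or plasma cells, epithelial tumour cells, fibroblasts, endothelial cells, mast cells or basophils, eosinophils and erythroid cells. The alternatives covered the cell minimum, cell calling, the choice of cells, doublets, thinning, scaling, free RNA, the gene minimum, the added count, clustering, the mitochondrial maximum and the control library.

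The ratio and list steps were tested on Poisson counts drawn around the summed counts of the control or wild-type library at the real depths. Cells, cell calling, clustering, free RNA and variation between libraries were not simulated. The counts below therefore cover counting error only and do not measure how often unperturbed libraries differ 2-fold. For trametinib against control, with 3090 genes, 49 of 49 genes lowered 4-fold and 50 of 50 raised 4-fold were past 2-fold, and 0 of 2892 unchanged genes were. For knockout against wild type, with 3287 genes, 50 of 50 were found each way and 0 of 3089 unchanged genes were. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0 and matplotlib 3.10.9.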

Results

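Neutrophils were isolated from MOC1 tumours, a mouse model of oral cavity cancer, and their transcripts were counted by droplet-based single-cell RNA sequencing of transcript 3′ ends. There were 4 libraries, each from cells of 3 mice combined and each the only library of its group. The groups were control, trametinib (an inhibitor of the kinase MEK, which activates ERK), Egr1 wild type and Egr1 knockout. Egr1 encodes an immediate early transcription factor that is induced through ERK. The matrices held 7849959 unique molecular identifiers (UMIs) in the control library, 4220828 in the trametinib library, 7092197 in the Egr1 wild-type library and 4189198 in the knockout library. With 1 library per group no difference between groups had a replicate check and no test was made. Each difference below is between libraries, and each 95% interval covers counting error only.

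Neutrophil-like cells were the main class in every library. They made up 74.0% of 6838 control cells (exact binomial 95% interval 72.9 to 75.0), 85.9% of 1620 trametinib cells (84.1 to 87.6), 73.7% of 5083 Egr1 wild-type cells (72.4 to 74.9) and 87.4% of 1421 knockout cells (85.6 to 89.1). Isolation for Ly6G, a neutrophil surface protein, sets these shares, and so does the minimum of 300 UMIs per cell. The median neutrophil-like cell held 376 UMIs in the control library, 1002 in the trametinib library, 371 in the wild-type library and 1132 in the knockout library. With a minimum of 100 UMIs the 4 shares were 85.2, 85.0, 85.4 and 84.7%, so the order of the libraries was not kept. Epithelial tumour-like cells made up 5.44, 6.30, 10.5 and 6.54% of cells in the same order, and macrophage or monocyte-like cells 4.28, 3.89, 5.31 and 1.76%. Fibroblast-like cells made up 0.790, 0.741, 1.24 and 1.34%. An unnamed cluster led by H2-Aa and complement C1q genes held 13.9, 1.17, 8.44 and 0.633%. Its leading genes held 3 macrophage or monocyte markers (C1qa, C1qb, C1qc) and 3 dendritic markers (H2-Aa, H2-Ab1, Cd74), a tie that left it unnamed. It had 951 control and 429 wild-type cells, more than the 293 and 270 named macrophage or monocyte-like. The macrophage or monocyte-like shares leave out any such cells in it, so they do not compare macrophage content between libraries.

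The neutrophil-like cells of different libraries lay in different clusters. Clusters 6, 8 and 19 held 87.9% of the neutrophil-like cells of the trametinib library and 93.7% of those of the knockout library. They held 0.692% of those of the control library and 0.507% of those of the Egr1 wild-type library, whose cells lay in clusters 1, 2, 3, 4 and 7. Values within the class were compared over all of these clusters.

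Egr1 was measured first in every library, because its level checks the knockout label. Egr1 (ENSMUSG00000038418, chromosome 18, 34859823 to 34864984, plus strand, GRCm38) had 2999 CPM of the neutrophil-like UMIs in the control library (exact Poisson 95% interval 2927 to 3072) and 1486 CPM in the Egr1 wild-type library (1427 to 1546). It had 145 CPM in the trametinib library (126 to 166) and 43.6 CPM in the knockout library (33.7 to 55.5). The log2 ratio was -4.37 for trametinib over control (-4.57 to -4.17) and -5.08 for knockout over wild type (-5.47 to -4.74). After each cell was thinned to 300 UMIs, 54.2% of control, 4.17% of trametinib, 31.6% of wild-type and 1.45% of knockout neutrophil-like cells had an Egr1 UMI; before thinning the shares were 64.2, 11.8, 40.1 and 4.35%. Barcodes of 1 to 20 UMIs, which hold free RNA, had 1830, 387, 951 and 46.6 CPM of Egr1 in the same order. At the estimated share of free RNA in neutrophil-like UMIs, 16.7% in the trametinib and 3.97% in the knockout library, free RNA would bring 64.6 of the 145 CPM and 1.85 of the 43.6 CPM, so it accounts for only part of these levels. The 16.7% is raised by 1 cell rich in haemoglobin, with 1566 of the 1608 Hbb-bs UMIs. The labels do not give the knockout allele, and the 3′ reads may lie outside its deleted part.

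Egr1 and ERK target genes in the other classes did not all go with the labels. In epithelial tumour-like cells Egr1 had 800, 577, 610 and 108 CPM in the control, trametinib, wild-type and knockout libraries, and Dusp6, a phosphatase induced by ERK that inactivates it, had 188, 152, 230 and 21.1 CPM. Etv4, another ERK target, had 41.9, 38.0, 47.5 and 10.5 CPM there. The 20 genes of the ERK-dependent feedback list without Bcl2l11 went both ways there. For trametinib over control the interval of the log2 ratio lay below 0 for 5 of them and above 0 for 4, and for knockout over wild type below 0 for 7 and above 0 for 2. Spred2 had 129, 58.6, 166 and 52.7 CPM and Spred1 had 91.7, 50.2, 108 and 47.1 CPM, whereas Phlda1 had 288, 570, 242 and 321 CPM and Fosl1 had 51.2, 123, 51.5 and 55.8 CPM. These cells lay in different clusters by library. Cluster 9 held 200 of 372 control and 338 of 535 wild-type cells but 24 of 102 trametinib and 3 of 93 knockout cells, whereas cluster 16 held 0, 45, 0 and 51 cells of the control, trametinib, wild-type and knockout libraries. Within cluster 16 the log2 ratio of Dusp6 for knockout over trametinib was -3.09 (-3.79 to -2.49), and within cluster 13, with 34 and 27 cells, it was -1.92 (-3.34 to -0.80). In macrophage or monocyte-like cells Dusp6 was low in both, at 12.6 CPM (5 UMIs) in the trametinib library against 86.4 in the control. It had 0 of 155359 UMIs in the knockout library, with an exact Poisson upper limit of 23.7 CPM. Egr1 went with the labels in these cells, at 1398 CPM in the control, 40.4 in the trametinib and 1677 in the wild-type library. The knockout library had 0 UMIs of Egr1 there. Macrophage or monocyte-like cells also lay in different clusters, mostly cluster 10 in the unperturbed and cluster 12 in the perturbed libraries. Fibroblast-like cells held Egr1 in all 4 libraries, at 1682, 616, 1735 and 312 CPM. Because of these values the perturbed libraries are called the trametinib-labelled and the knockout-labelled library from here on, and every direction drawn from them rests on those labels.

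**Figure D1:**
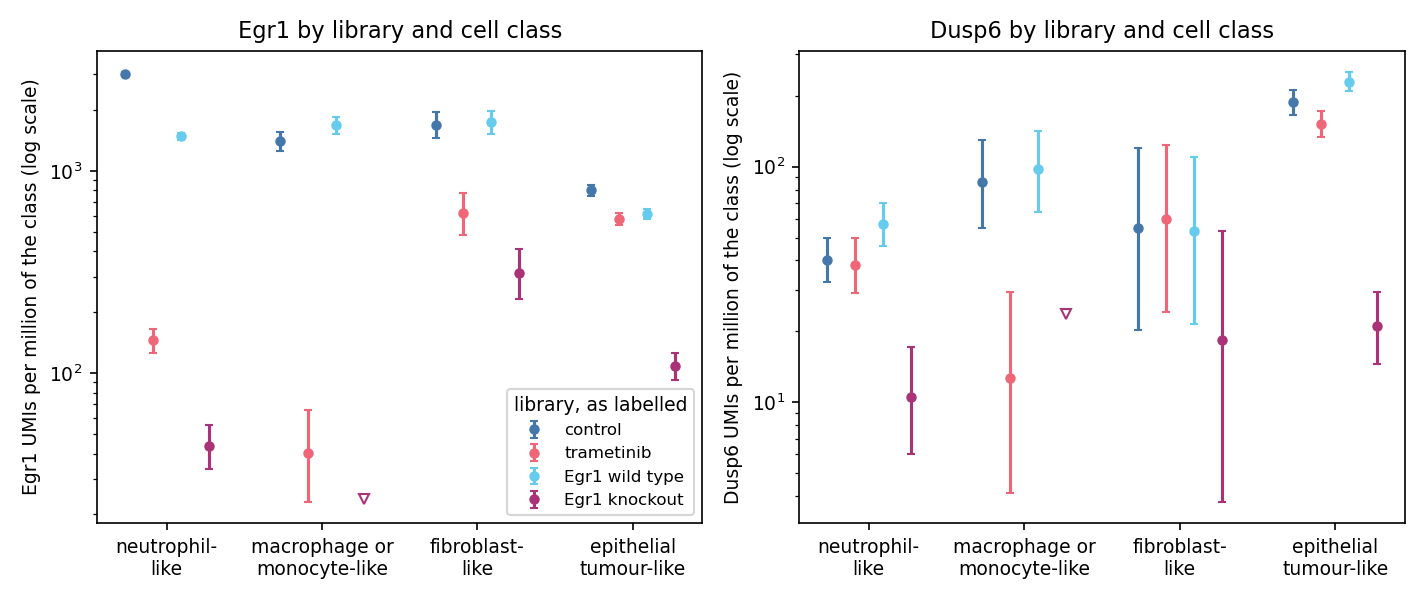
Egr1 (left) and Dusp6 (right) in CPM of each cell class on a log scale, by library as labelled. Points are the summed count of 1 library with exact Poisson 95% intervals that cover counting error only, and open triangles are upper limits where no UMI was counted; in epithelial tumour-like cells Dusp6 was 152 CPM in the trametinib library and 21.1 CPM in the knockout library.

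The drug comparison asked how neutrophils of the tumour differ under MEK inhibition. Neutrophil-like cells of the trametinib-labelled library had lower levels of immediate early, hypoxia and glycolysis, and interferon response genes than those of the control library. Il1b, which encodes interleukin-1β, had 2782 CPM against 14847 (log2 ratio -2.42), and Hk2, which encodes the glycolytic enzyme hexokinase 2, had 60.7 against 445 (-2.87). Hmox1, which encodes haem oxygenase 1, was higher at 978 against 175 CPM (2.48), as was Ftl1, which encodes ferritin light chain, at 18560 against 5231 (1.83). Of 3518 genes in the comparison, 557 were at least 2-fold higher and 452 at least 2-fold lower in the trametinib-labelled library.

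Of 22 measured immediate early genes, 15 were at least 1.5-fold lower in the trametinib-labelled library and 5 higher. Their median log2 ratio was -1.37, at percentile 0 of 10000 random lists matched on expression. Fos, a subunit of the AP-1 transcription factor, had 49.2 against 667 CPM (-3.75), Egr3 had 4.72 against 159 (-4.97) and Fosb had 32.4 against 258 (-2.98). Of 31 hypoxia and glycolysis genes, 23 were lower and 0 higher, with a median of -1.23 at percentile 0. Slc16a3, a lactate transporter, had 74.2 against 433 CPM (-2.54), Egln3, an oxygen-sensing hydroxylase, had 57.3 against 326 (-2.50) and Vegfa, an angiogenic factor, had 47.9 against 170 (-1.82). The glucose transporter gene Slc2a1 had 137 against 333 CPM (-1.28). Of 5 measured ERK-dependent feedback genes, 2 were lower, with a median of -0.35 at percentile 19.3, and Dusp6 itself, under the minimum of 50 CPM, had 38.4 against 40.4 CPM. That list mixes directions, since Bcl2l11 is repressed through ERK, and it had 970 against 719 CPM (0.43). The other measured members had ratios below 0: Ier3 (-1.03), Mcl1 (-0.71), Phlda1 (-0.35) and Dusp5 (213 against 248 CPM).

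Of 30 interferon response genes, 25 were lower in the trametinib-labelled library, with a median of -1.01 at percentile 0. Cxcl10, a chemokine induced by interferon, had 53.9 against 452 CPM (-3.06). The same list was also lower in the Egr1 wild-type library than in the control, as given with that comparison. Of 26 inflammatory cytokine and NF-kB genes, 12 were lower and 5 higher (median -0.49, percentile 0.65). Cxcl2, a chemokine that attracts neutrophils, had 8580 against 20989 CPM (-1.29), Ccl2 had 18.9 against 143 (-2.90) and Osm, which encodes the cytokine oncostatin M, had 14.2 against 168 (-3.54). Of 16 immunosuppression and reactive oxygen genes, 8 were lower and 4 higher (median -0.55, percentile 1.69). Among them Ptgs2, which encodes cyclooxygenase-2, had 79.6 against 846 CPM (-3.41) and Nos2, the inducible nitric oxide synthase, had 8.77 against 159 (-4.13). Arg2 had 750 against 492 CPM (0.61) and Cd274, which encodes PD-L1, had 893 against 1124 (-0.33). Of 16 antigen presentation genes, 8 were lower and 0 higher (median -0.58, percentile 0.98), with the costimulatory gene Cd86 at 21.6 against 107 CPM (-2.29). H2-Aa, at -1.98, is also a marker of dendritic cells. After free RNA was subtracted it came to 0.69, the same value as H2-Ab1, which rests on the added count and gives no direction.

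Among neutrophil identity genes, 8 of 14 were lower and 1 higher in the trametinib-labelled library (median -0.73, percentile 0.63), including G0s2 at 684 against 3941 CPM (-2.53) and the chemokine receptor gene Cxcr2 at 107 against 320 (-1.58). S100a8, which encodes a subunit of calprotectin, had 7291 against 12105 CPM (-0.73). Of 18 tumour-associated neutrophil genes, 7 were higher and 3 lower (median 0.36, percentile 96.1), with Fnip2 at 1902 against 230 CPM (3.05) and Spp1, which encodes osteopontin, at 1080 against 319 (1.76). Siglecf had 51.3 against 50.2 CPM. Of 8 immature neutrophil granule genes, 7 were higher (median 1.35, percentile 99.9), led by Camp at 404 against 3.59 CPM (6.73) and Ngp at 939 against 20.6 (5.49). These came from few cells: 561 of the 599 Camp UMIs and 1356 of the 1392 Ngp UMIs of the trametinib-labelled library lay in 16 cells of cluster 19, and without that cluster the list had 4 measured genes with a median of 0.11.

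Of 12 unfolded protein and heat shock genes, 8 were higher in the trametinib-labelled library (median 1.09, percentile 99.97), with Herpud1, a gene of the endoplasmic reticulum stress response, at 183 against 23.8 CPM (2.93). Hspa1a (2.09) and Hspa1b (1.75) are near-identical copies whose reads may be split between them. Of 17 apoptosis and survival genes, 9 were higher and 6 lower (median 0.66, percentile 99.2): the death receptor gene Fas had 363 against 108 CPM (1.75), the cell cycle inhibitor gene Cdkn1a had 202 against 1121 (-2.47) and Mcl1 had 1720 against 2809 (-0.71). Of 18 lysosome and lipid genes, 8 were higher and 4 lower (median -0.06, percentile 37.3), with Ctsd, which encodes cathepsin D, at 1900 against 477 CPM (1.99). Of 4 measured cell cycle genes, 3 were higher (median 1.05, percentile 97.9), and the proliferation marker Mki67 had 135 against 25.1 CPM (2.42). Of 17 migration and adhesion genes, 5 were lower and 4 higher (median -0.39, percentile 3.61), with Cd44 at 1189 against 3072 CPM (-1.37). Of 16 EGR1 target genes, 7 were higher and 6 lower (median 0.04, percentile 56.7). Of 5 RNA quality and stress genes, 1 was higher, Gm26917 at 149 against 8.52 CPM (4.09), and the median was -0.44 (percentile 16.5).

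The largest ratios included genes of blood. Hbb-bs, a β-globin gene, had 1084 against 31.8 CPM (5.08), but 1566 of its 1608 UMIs lay in 1 trametinib-labelled cell and its ratio turned to -1.56 at a minimum of 500 UMIs per cell. Hba-a1 and Hba-a2, near-identical α-globin copies, also took most of their UMIs from 1 cell (506 of 523 and 452 of 462). Without cells of 20 or more haemoglobin or immunoglobulin UMIs the log2 ratios were 4.68 for Hbb-bs, 4.13 for Hba-a1 and 4.98 for Hba-a2, on few UMIs. Barcodes of 1 to 20 UMIs held 720 CPM of Hbb-bs in the trametinib-labelled library and 7.32 in the control. Of the erythroid markers 4 were measured and 4 higher, with a median of 4.51. The immunoglobulin genes Igkc and Ighg2c were at 0 UMIs in the trametinib-labelled library, at least 129-fold and at least 49.9-fold lower against a floor of 3 counts; 572 of 583 Igkc UMIs and 220 of 225 Ighg2c UMIs of the control library lay in 1 cell. Without cells of 20 or more haemoglobin or immunoglobulin UMIs the log2 ratios came to -3.93 for Igkc and -2.87 for Ighg2c, values that rest on the added count. Rmi2 rested on 3 control UMIs (log2 ratio 5.89, 4.53 to 8.41). Among other large ratios, Mpp7 had 54.6 against 1254 CPM (-4.51), Per2, a gene of the circadian clock, had 4.72 against 74.5 (-3.88) and Oscp1 had 193 against 4.04 (5.50).

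Markers of other cell types in the neutrophil-like cells also differed in this comparison. Of 9 measured neutrophil markers, 7 were lower in the trametinib-labelled library (median -0.74). Of 5 macrophage or monocyte markers, 1 was higher and 2 lower (median 0.00), of 3 dendritic markers 3 were lower (median -1.16), and of 5 epithelial tumour markers 1 was higher (median 0.05). The endothelial list had 1 measured gene, Pecam1, which was higher, and the B or plasma cell list had 1, Igkc, which was lower. T cell, NK cell, fibroblast, mast or basophil and eosinophil markers had 0 measured genes in every comparison. The sex-linked list had 2 measured genes. Ddx3y, a Y-linked gene, had 87.0 CPM in the control library and 0 UMIs in the neutrophil-like cells of each other library, at least 43.0-fold lower in the trametinib-labelled one. Xist, the non-coding RNA of the inactive X chromosome, had 163, 342, 464 and 434 CPM in the control, trametinib-labelled, Egr1 wild-type and knockout-labelled libraries.

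The genotype comparison asked how tumour neutrophils without Egr1 differ, and the design names states that depend on hypoxia and on Egr1. Neutrophil-like cells of the knockout-labelled library had lower levels of immediate early, hypoxia and glycolysis, and interferon response genes than those of the Egr1 wild-type library. Il1b had 1918 against 15186 CPM (log2 ratio -2.98), Hk2 had 42.9 against 367 (-3.09) and Fos had 33.0 against 747 (-4.49). Hmox1 was higher at 1067 against 146 CPM (2.87), as was Fnip2 at 2162 against 217 (3.31). Of 3780 genes, 601 were at least 2-fold higher and 500 at least 2-fold lower in the knockout-labelled library.

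Of 22 immediate early genes, 16 were lower and 2 higher in the knockout-labelled library (median -1.75, percentile 0), with Ier2 at 76.0 against 647 CPM (-3.08) and Egr3 at 5.95 against 106 (-4.08). Of 31 hypoxia and glycolysis genes, 25 were lower and 1 higher (median -1.44, percentile 0). Hilpda, which encodes a hypoxia-induced lipid droplet protein, had 74.7 against 936 CPM (-3.64), the glycolytic enzyme gene Pgam1 had 80.6 against 547 (-2.76), Vegfa had 42.9 against 212 (-2.30) and Slc2a1 had 91.8 against 315 (-1.78). Of 6 ERK-dependent feedback genes, 5 were lower (median -0.98, percentile 2.53); Dusp6 was at -2.39 (-3.30 to -1.66), and Bcl2l11, which encodes the pro-apoptotic protein BIM and is repressed through ERK, was higher at 1161 against 526 CPM (1.14). Of 15 EGR1 target genes, 7 were lower and 5 higher (median -0.53, percentile 2.56).

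Of 27 interferon response genes, 18 were lower in the knockout-labelled library (median -1.06, percentile 0), including the antiviral gene Rsad2 at 43.6 against 253 CPM (-2.53) and Cxcl10 at 68.1 against 312 (-2.19). Of 25 inflammatory cytokine and NF-kB genes, 12 were lower and 4 higher (median -0.52, percentile 0.52). Osm had 5.29 against 205 CPM (-5.19), the chemokine gene Cxcl3 had 12.6 against 200 (-3.96) and Cxcl2 had 4993 against 16786 (-1.75). Of 15 immunosuppression and reactive oxygen genes, 5 were lower and 3 higher (median 0.14, percentile 70.6), with Ptgs2 at 42.3 against 736 CPM (-4.11), Arg2 at 644 against 388 (0.73) and Cd274 at 947 against 707 (0.42). Of 14 antigen presentation genes, 4 were lower and 3 higher (median 0.12, percentile 69.9): the costimulatory gene Cd80 had 97.8 against 772 CPM (-2.98) and Nlrc5, an activator of class I genes, had 188 against 78.0 (1.26).

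Of 14 neutrophil identity genes, 7 were lower and 1 higher in the knockout-labelled library (median -0.75, percentile 0.43). G0s2 had 468 against 3805 CPM (-3.02) and Il1r2, a decoy receptor of interleukin-1, had 976 against 4711 (-2.27), whereas S100a8 had 8486 against 8951 (-0.08). Of 18 tumour-associated neutrophil genes, 4 were higher and 3 lower (median 0.01); Siglecf had 61.4 against 84.2 CPM (-0.45) and Ccl4 had 776 against 2228 (-1.52). Of 6 immature neutrophil granule genes, 4 were higher (median 1.20, percentile 94.3); without cluster 19 the list had 4 measured genes, of which 2 were higher, with a median of 0.71. Ngp fell from 3.99 to 0.28 without that cluster, since 103 of its 111 knockout-labelled UMIs lay in 1 cell. Camp rested on 3 wild-type UMIs (5.28, 3.92 to 7.79), and 77 of its 127 knockout-labelled UMIs lay in 1 cell. Of 14 unfolded protein and heat shock genes, 7 were higher (median 0.56, percentile 98.8), with Herpud1 at 206 against 29.7 CPM (2.78). Of 17 apoptosis and survival genes, 7 were higher and 5 lower (median 0.08, percentile 55.3), with Fas at 466 against 76.8 CPM (2.60) and the survival gene Bcl2l1 at 151 against 595 (-1.98). Of 18 lysosome and lipid genes, 7 were higher and 4 lower (median 0.03, percentile 53.1): the cholesterol transporter gene Abcg1 had 340 against 71.8 CPM (2.24) and Ftl1 had 17793 against 5254 (1.76). Of 17 migration and adhesion genes, 6 were lower and 2 higher (median -0.10, percentile 28.6).

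Of 5 cell cycle genes, 3 were higher and 1 lower in the knockout-labelled library (median 1.03, percentile 97.8), with Mki67 at 188 against 14.2 CPM (3.69), and the median turned to -0.53 over all called cells. Of 5 RNA quality and stress genes, 1 was higher and 1 lower (median -0.25, percentile 28.0). Among markers of cell types, 5 of 9 neutrophil markers were lower (median -1.81), 2 of 3 macrophage or monocyte markers were higher (median 0.92), 1 of 2 dendritic markers was lower, 3 of 6 epithelial tumour markers were lower (median -0.71) and the 1 measured endothelial marker was higher. Erythroid and B or plasma cell markers had 0 measured genes. Other large ratios were those of Mrnip (482 against 23.5 CPM, 4.34), Hip1r (480 against 24.2, 4.29) and Ifitm10 (213 against 6.19, 5.03), and of Stat4 (3.96 against 72.5, -4.08) and Cass4 (36.3 against 585, -4.00). Cd247 rested on 1 wild-type UMI (6.15, 4.21 to 12.04).

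**Figure D2:**
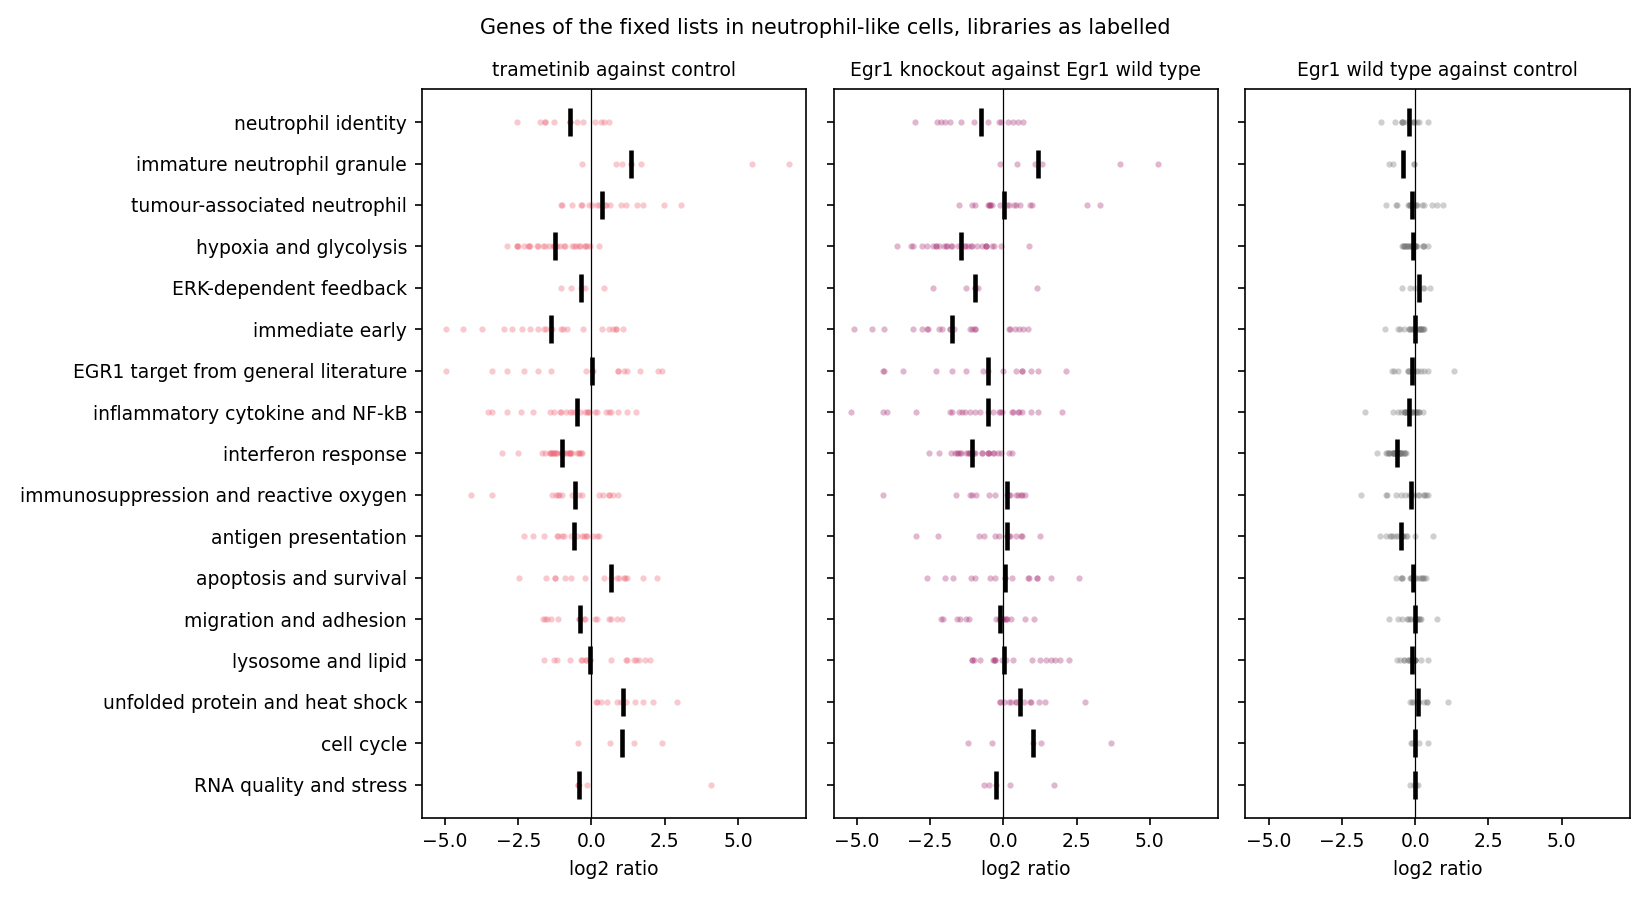
Log2 ratios of the genes of each fixed list in neutrophil-like cells, with 1 panel per pair of libraries as labelled; dots are genes and black bars are the medians of the lists. The hypoxia and glycolysis median lay at -1.23 for trametinib over control, at -1.44 for knockout over wild type and at -0.07 for wild type over control.

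The Egr1 wild-type and control libraries, which had neither perturbation, served as the background measured in the same way. They differed at least 2-fold in 28 of 3311 genes, with 10 higher and 18 lower in the Egr1 wild-type library. Scaling by the median gave 6 higher and 34 lower, and TMM scaling, which moved the log2 ratios by 0.17, gave 3 and 46. Interferon response genes were lower in the Egr1 wild-type library, with 17 of 30 past 1.5-fold and a median of -0.63 (percentile 0; -0.79 with TMM scaling). Of 16 antigen presentation genes, 7 were lower and 1 higher (median -0.47, percentile 0), and of 3 dendritic markers 3 were lower (median -0.82). Epithelial tumour markers went the other way, with 1 of 6 higher and 0 lower (median 0.45, percentile 99.25). Inflammatory cytokine and NF-kB genes (median -0.21, percentile 0.01) and neutrophil identity genes (median -0.22, percentile 0.42) were also slightly lower, with 2 of 26 and 2 of 14 past 1.5-fold. Hypoxia and glycolysis genes had 0 of 31 past 1.5-fold (median -0.07, percentile 1.22), and immediate early genes had 1 of 22 (median -0.00, percentile 27.7). Egr1 itself was lower in the Egr1 wild-type library, as given above, so the unperturbed libraries were not alike in it.

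The differences of the drug and the genotype comparison were largely the same across genes. Pearson's r of the log2 ratios across 3403 genes was 0.917 and Spearman's rho was 0.898, with a covariance of 1.11. Genes are not independent replicates, and the comparisons shared no library. Among these genes 419 were at least 2-fold higher in both, from 523 and 541 in each, where independent lists would share 83.1. Another 327 were at least 2-fold lower in both, from 419 and 459, where independent lists would share 56.5, and 0 went opposite ways past 2-fold. Set directly against each other, the knockout-labelled and trametinib-labelled libraries differed at least 2-fold in 54 of 3386 genes. Since control and Egr1 wild type resembled each other and both perturbed libraries held fewer and deeper cells, an unlabelled batch and the perturbations cannot be told apart in this design.

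**Figure D3:**
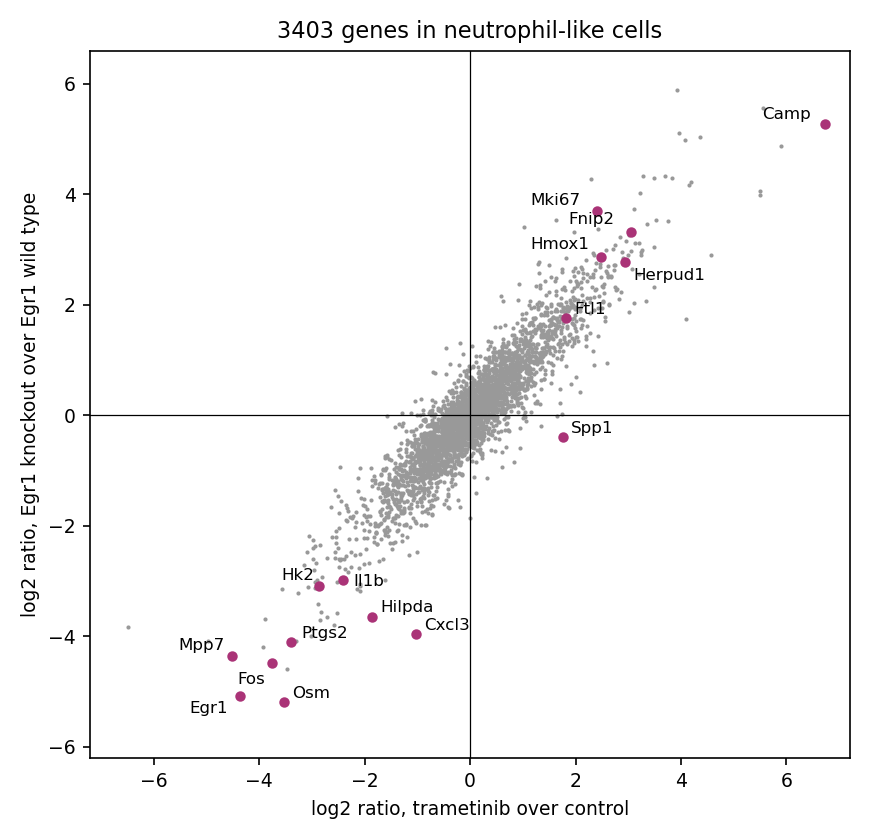
Each dot is 1 of 3403 genes in neutrophil-like cells, at its log2 ratio of trametinib over control (horizontal) and of knockout over wild type (vertical), libraries as labelled; named genes are in purple. The dots lie along the diagonal, with a Pearson's r of 0.917 across genes.

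Within libraries, cells with an Egr1 UMI were set against cells without one, all thinned to 300 UMIs, and Egr1 itself was left out of the lists. Some Egr1 UMIs may come from free RNA. At the estimated shares it would bring 142 of 2999 CPM in the control and 57.5 of 1486 in the wild-type library. In the trametinib-labelled library it would bring 64.6 of 145 CPM, and in the knockout-labelled library 1.85 of 43.6. By these estimates it is a small part except in the trametinib-labelled library. The estimate for that library is raised by haemoglobin, since 1 neutrophil-like cell held 1566 of its 1608 Hbb-bs UMIs. Hypoxia and glycolysis genes were 1.13 times as high in control cells with an Egr1 UMI (1.10 to 1.16) and 1.16 times as high in such cells of the Egr1 wild-type library (1.12 to 1.20). Immediate early genes were 1.17 and 1.24 times as high, inflammatory genes 1.09 and 1.16 times and interferon response genes 0.983 and 1.01 times. The knockout-labelled library had 18 cells with an Egr1 UMI and the trametinib-labelled library had 58. There the ratio for hypoxia and glycolysis genes was 1.79 (1.36 to 2.31) and 1.56 (1.35 to 1.79), and for immediate early genes 1.84 (1.44 to 2.31) and 1.98 (1.76 to 2.22). For inflammatory genes it was 1.43 (1.24 to 1.65) and 1.60 (1.49 to 1.71), and for interferon response genes 1.38 (0.993 to 1.86) and 1.13 (0.948 to 1.33). The ratios changed with the thinning. At 500 UMIs those for hypoxia and glycolysis genes were 1.05 (1.00 to 1.10) in the control and 1.08 (1.02 to 1.14) in the wild-type library. They were 1.43 in the knockout-labelled and 1.30 in the trametinib-labelled library. For immediate early genes the ratios at 500 UMIs were 1.20, 1.24, 1.51 and 1.89 in that order.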

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

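The tests at 100 UMIs, over every barcode, across cell types, of ERK targets in epithelial tumour-like cells and of Igkc in 1 cell were chosen only after the result was seen.

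Barcodes of at least 100 but under 300 UMIs, which the comparisons left out, held neutrophil transcripts above the level of free RNA. Neutrophil markers made up 3.64% of their UMIs in the control library, 1.95% in the trametinib-labelled, 3.47% in the Egr1 wild-type and 2.29% in the knockout-labelled library. In barcodes of 1 to 20 UMIs the shares were 2.26, 0.901, 1.64 and 1.03%. There were 7970, 269, 7452 and 284 such barcodes.

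The drug and genotype comparisons shared most of their differences, with a Pearson's r of 0.917 across genes. The tables argue against free RNA as the whole cause, since r was 0.819 after it was subtracted, and against 1 shift of the same genes in every cell type, since neutrophil-like and epithelial tumour-like ratios were correlated at no more than 0.384, near the 0.359 of the unperturbed libraries; a shift shared with macrophage or monocyte-like cells, where r was 0.508 and 0.520 against 0.131 for the unperturbed libraries, stays open. They also argue against selection of deep cells by the 300-UMI minimum as the whole cause, which would need r below 0.5: r was 0.923 at 100 UMIs, 0.843 over every barcode and 0.787 at 100 UMIs with thinning to 100, the last short of the bound of 0.8 written for it before that value was seen. An unlabelled batch that joins the control with the wild-type library and both perturbed libraries is also open, because the design confounds it with the perturbations. A MEK-dependent role of Egr1 may give shared differences too, as an untested hypothesis.

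In epithelial tumour-like cells the knockout-labelled library, not the trametinib-labelled one, had the lowest Dusp6 and Etv4. Its Egr1 was also the lowest. Correct labels give that direction only if the knockout covers the tumour cells, which the labels do not say. Egr1 was lower in the knockout-labelled than in the trametinib-labelled library in neutrophil-like (43.6 against 145 CPM), epithelial tumour-like (108 against 577) and fibroblast-like cells (312 against 616). Macrophage or monocyte-like cells had 0 of 155359 UMIs against 40.4 CPM. If the labels of the perturbed libraries were exchanged, ERK targets would be lower in the knockout-labelled library in every class, as Dusp6 was in neutrophil-like cells, at 10.6 against 38.4 CPM. The ERK feedback list without Bcl2l11 had a median log2 ratio of -0.46 for knockout-labelled over trametinib-labelled epithelial tumour-like cells, at percentile 0.09 of matched lists, with 12 of 13 genes lower. The test set in advance, Dusp6 in fibroblast-like cells, gave -1.59 with an interval of -4.29 to 0.42. An exchange cannot be told apart from correct labels. That interval holds 0, and Dusp6 was low in macrophage or monocyte-like cells of both libraries, on 5 trametinib-labelled and 0 knockout-labelled UMIs. The Dusp6 levels there are between cells of different clusters, which limits them. Cluster 12 held 59 of 63 trametinib-labelled and 22 of 25 knockout-labelled cells, and cluster 10 held 222 of 293 control cells. The 20 genes of the list went both ways in trametinib-labelled epithelial tumour-like cells against the control. Of them 5 were lower beyond counting error, such as Spred2 (58.6 against 129 CPM), and 4 higher, such as Phlda1 (570 against 288). The allele is not given, so the Egr1 levels of the classes do not decide either. An allele deleted only in some cells could also leave Egr1 in others.

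The control library alone had Y-linked and most immunoglobulin transcripts in its neutrophil-like cells. Free immunoglobulin RNA would spread over cells, but 1 cell held 98.1% of the Igkc UMIs, which argues against it for most of them; the share in the 1% of cells with the most, 100%, decides nothing because 12 cells held any. Mice of both sexes in the control pool may account for the Y-linked genes and lower Xist. Ddx3y, Eif2s3y, Uty and Kdm5d had 194, 107, 97 and 15 UMIs in the control library. Of 373 cells with a Y-linked UMI and 311 with an Xist UMI, 12 had both where independence gives 22.9, a ratio of 0.523 (0.270 to 0.914). That is the direction separate male and female cells would give, but the interval is wide, so other causes were not excluded. Male mice in the control pool alone would make sex a further difference in both comparisons against the control. No biological explanation was tested.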

How the results depend on the processing

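The alternatives of 100 UMIs with or without thinning and those without some cells or clusters were chosen only after the result was seen. No paired analysis was possible because each group had 1 library, and for the same reason neither a split of the samples nor a search for outlying samples was possible. Of the main results' values under the alternatives run, 251 counted as same as the main one, 36 as moved and 0 as reversed. For named genes the counts were 3480, 681 and 15, and for other lists 1072, 36 and 2. Shares of neutrophil-like cells and ratios between cells with and without an Egr1 UMI were less stable, with 29 same and 23 moved. Some alternatives could hardly move a value, so their labels of same say little. Removal of doublets, for example, kept 1389 of 1392 trametinib-labelled and 1235 of 1242 knockout-labelled neutrophil-like cells. Same does not mean close for lists, whose medians had wide intervals over genes. The immediate early median for knockout over wild type, -1.75 (-2.60 to 0.20), counted as same at -0.66 over all called cells. The immature neutrophil granule median for trametinib over control, 1.35, counted as same at 0.11 without cluster 19. The hypoxia and glycolysis median ranged from -1.34 to -0.68 for trametinib over control and from -1.70 to -1.09 for knockout over wild type, and the immediate early median from -1.55 to -0.69 and from -1.86 to -0.66. The cause of the changes below was not tested except where stated. Depth limits the libraries unequally, since the median neutrophil-like cell of the unperturbed libraries held 376 and 371 UMIs.

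The count of genes 2-fold different between wild type and control, 28, became 85 at a minimum of 500 UMIs, 176 at a minimum per library, 18 at 100 UMIs, 49 with TMM scaling, 85 over all called cells, 108 at a minimum of 20 CPM and 14 at 100 CPM. The genes 2-fold higher for trametinib over control, 557, became 365 with every barcode, 320 over all called cells, 367 at 100 CPM and 904 at 20 CPM. At 20 CPM, where more genes enter, 742 were lower in that comparison, and 934 were higher and 806 lower for knockout over wild type. Pearson's r, 0.917, became 0.893 at 500 UMIs, 0.859 at a minimum per library, 0.923 at 100 UMIs, 0.787 at 100 UMIs with thinning to 100, 0.843 with every barcode, 0.807 over all called cells, 0.885 with cells thinned to 300 UMIs, 0.819 with free RNA subtracted, 0.887 at 20 CPM, 0.933 at 100 CPM, 0.880 with the controls exchanged and 0.910 without cluster 1, with 22.7% of control and 40.4% of wild-type neutrophil-like cells, which haemoglobin genes lead when no minimum share of cells is asked. Of the genes past 2-fold that were also measured at 100 UMIs with thinning, 478 of 478 higher and 428 of 431 lower ones kept their sign for trametinib over control, and 502 of 502 and 470 of 473 for knockout over wild type; 417, 328, 419 and 355 of them stayed past 2-fold. The Egr1 log2 ratio of trametinib over control became -4.93 at a minimum per library, -3.74 at 100 UMIs with thinning, -2.65 with every barcode, -2.39 over all called cells, -5.04 with free RNA subtracted and -3.35 with the other control. That of knockout over wild type became -3.81, -3.57 and -6.09 with every barcode, all called cells and the other control, and -4.68 with cells thinned to 300 UMIs.

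The reversed values for trametinib over control were those of Hbb-bs (-1.56), Hba-a2 (-2.30) and Hba-a1 (-1.92) at 500 UMIs and of the same genes (-0.51, -1.22 and -0.75) without cluster 1. Without cells of 20 or more haemoglobin or immunoglobulin UMIs they stayed at 4.68, 4.98 and 4.13. H2-Aa and H2-Ab1 came to 0.69 each with free RNA subtracted, a shared value that rests on the added count. Chil3 turned to -0.43 without the cluster led by granule genes. Ighg2c turned to 0.21 at 100 UMIs with thinning. With the other control, Ighg2c and Ddx3y came to 0.12, where the value rests on the added count, and Xist to -0.44. For knockout over wild type, H2-Ab1 turned to 0.61 with free RNA subtracted, Gm42418 to 0.17 at 100 UMIs with thinning, and the cell cycle median to -0.36 with every barcode and -0.53 over all called cells.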

Other observations

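The comparisons in other cell classes and between the comparisons were chosen only after the result was seen; the tests of gene span, of handling and of genes near Egr1 were set beforehand.

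Macrophage or monocyte-like cells, which take up debris and present antigen, differed in some of the same genes. The cells of the control and Egr1 wild-type libraries lay mostly in cluster 10, and those of the trametinib-labelled and knockout-labelled libraries mostly in cluster 12. Fos had 172 CPM in 63 trametinib-labelled cells against 1401 in 293 control cells, and 70.8 in 25 knockout-labelled cells against 1467 in 270 wild-type cells. Il1b had 973 against 1796 CPM and 566 against 1496, and Ftl1 had 14120 against 7180 and 11187 against 6447. Hk2 had 136 against 132 CPM and 90.1 against 138, with intervals of the log2 ratio that hold 0. The log2 ratios were correlated with those of neutrophil-like cells at 0.508 and 0.520 across genes.

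Epithelial tumour-like cells of the perturbed and unperturbed libraries lay mostly in different clusters: cluster 16 held 45 of 102 trametinib-labelled and 51 of 93 knockout-labelled cells and 0 of the unperturbed libraries, and cluster 9 held 200 of 372 control and 338 of 535 wild-type cells. With that limit they had lower Hk2 in both perturbed libraries, at 117 against 276 CPM and at 96.6 against 255, and higher Hmox1, at 126 against 46.2 and at 134 against 31.6. Their hypoxia and glycolysis list had a median log2 ratio of -0.17 for trametinib-labelled over control and of -0.73 for knockout-labelled over wild type.

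The genotype comparison was lower than the drug comparison in Cxcl3 (log2 ratios -3.96 and -1.03) and in Spp1 (-0.39 and 1.76). It was higher in the acute-phase gene Saa3 (3.40 and 1.02) and in the coagulation factor gene F10 (2.15 and 0.58). Saa3 also differed between the unperturbed libraries, at -1.83 for wild type over control, and F10 at -1.22. These differences were not tested.

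A few further tests of technical explanations came out against them in the form tested, with the limits given. With the median of each bin of gene span taken off, r between the comparisons was 0.920, so a trend with gene span does not account for it. Handling of the suspension that lowers immediate early genes in all cells would lower them in epithelial tumour-like cells of the knockout-labelled library. Their median log2 ratio there was 0.16 over 20 genes (-0.15 to 0.45), between cells of different clusters. Fos, 1 gene of the list, was lower there at -0.52 (-0.60 to -0.43) and in macrophage or monocyte-like cells at -4.31. Handling that acts on some cell classes only therefore stays open. A chromosome segment from another strain around Egr1 would set genes nearby apart: 27 genes within 10 Mb had a median absolute difference between the comparisons of 0.14, at percentile 1.12 of matched lists, whose median was 0.26. A median over 27 genes would not show a change in only a few of them.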
